A study of Mus musculus with 44 samples.

How the data were processed

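The series holds mRNA profiles of 44 single embryos at embryonic day 9.5, with the a1 and a2 alleles of miR-196 marked by GFP and the b allele unmarked. Per the labels' protocols, GFP-positive cells were sorted by flow cytometry from freshly dissected C57Bl/6 embryos, 200 ng of RNA per embryo went into an unstranded TruSeq library, and 50 bp single-end reads were sequenced on a HiSeq instrument. The 10 genotype groups hold 5 embryos (4 groups) or 4 embryos (6 groups), grouped by the genotype and replicate number in the sample titles and characteristics. The file names carry a flow cell code, shared by 32 libraries of 7 groups and by 12 libraries of 3 groups, and a second short code whose meaning is not given in the sources used here.

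The authors aligned the reads with STAR (version 2.3.1n) to the mm10 build and estimated FPKM per gene for each library with Cufflinks (2.1.1), per the submitters' processing notes, and these FPKM values were used as deposited. The 7 comparison tables were made by the authors with Cuffdiff (2.1.1), per the same notes, and hold group FPKM, a log2 fold change written as control over mutant per the file headers, and a p-value and q-value per gene. The log2 fold changes of the authors' deposited tables were turned to mutant over control here. Values from those tables stand apart in the text, named as the authors' table, and have no SD. The deposited p-values and q-values were counted as they are, by the tables' own significance column and by a q below 0.01.

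Each library file lists FPKM for 22476 gene IDs. Lines of one gene ID were summed, and 22 genes whose estimate failed in any library were left out of the fits that held such a library. The files hold no read counts, so the count-based test that had been planned for that case was not used, and log2(FPKM + 1) was fitted with limma (3.58.1, R 4.3.3), with a trend and robust option in the moderated variance. Genes with a mean FPKM of at least 1 over the embryos of a fit were tested, and p was adjusted by Benjamini and Hochberg with a threshold of 0.05. Depth per library is unknown. As a relative measure, the ratio at which the lowest FPKM values of 2 libraries pile up was used, taken as genes with 1 read in both.

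There were 10 comparisons of 2 groups, 7 of them those for which the authors deposited a table, and 3 further fits: the a2 effect common to the wild-type and heterozygous a1 backgrounds, the difference of the a2 effect between them, and the slope per mutant allele across 3 groups. Each comparison used the libraries of its own groups and no covariate. Comparisons between a b genotype and the a2 heterozygotes cross flow cells. Those comparisons also share their control group, so their gene lists are not independent of each other.

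Gene lists were written for 34 themes, covering miR-196 targets, neighbours of the targeted genes, Hox groups, tissues of the embryo, signalling, metabolism and stress, and 33 had at least 3 tested members. Each was tested with camera (limma, preset correlation of 0.01), adjusted over the lists of a comparison, and again with a correlation estimated from the residuals and with fry. Camera asks whether a list ranks apart from other genes. Fry, used in its directional form, asks whether the members of a list shift together in 1 direction, without regard to other genes. Members past the threshold were counted over all genes and again with p adjusted over the list alone. The mean log2(FPKM + 1) of the 8 Hox targets per embryo was compared with exact two-sided permutation tests. Genes with a miR-196 site (an 8mer or a 7mer matching positions 2 to 8) in the longest annotated 3′ UTR (GENCODE M21) formed 1 set, tested with camera. Of the 22476 gene IDs 20304 had an annotated 3′ UTR, and the others were not searched.

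The genes named in the report were chosen by a rule: all Hox targets; the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap; up to 4 members of a list past the threshold over all genes or over the list alone, by smallest adjusted p; and, where fewer than 10 genes passed, the 5 genes with the smallest p in each direction. Genes with provisional names gave their place to the next. Some genes that meet the rule are not reported here. Genes named outside it are said to be so. The groups, tests, thresholds, lists, rule and alternatives were fixed before the data were examined, except where the text says that a choice was made later.

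Results were recomputed with 1 choice changed at a time. All fits were run with a pseudocount of 0.1, no filter, libraries rescaled by the median ratio to their geometric mean, and each library left out in turn. The 10 comparisons of 2 groups were also run with a mean FPKM of at least 5, quantile normalization, all 44 libraries in 1 fit and the replicate number as a block. The second code of the file names was a covariate in the 8 fits inside the first flow cell alone. In the comparisons with a b genotype it could not be used, since the groups share no code or hold a single one. The exact tests of the Hox target mean were repeated with the pseudocount, the rescaling and each library left out, and the seed-matched set with the rescaling and other site definitions. Other splits of the embryos of each fit were counted (all 35 for 4 against 4, and otherwise 100 drawn at random). The procedure was tested on simulated data with 200 changed genes placed into values with the spread of a1 loss, a1 a2 double loss and a2 b double loss. It recovered 44%, 54% and 58% of genes changed 1.25-fold, 80%, 82% and 84% of those changed 1.5-fold and 98%, 100% and 96% of those changed 2-fold, with 4, 7 and 7 false calls. Genes were simulated independently of each other, without the structure that genes share in real embryos. These false calls may therefore understate those in the real data. No pair of libraries shared more than 0.0171% of identical FPKM values. Figures and tables were made with Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9).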

Results

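RNA was sequenced from GFP-positive cells sorted by flow cytometry from 44 single mouse embryos at embryonic day 9.5. The embryos carried loss-of-function alleles of miR-196, a microRNA family encoded inside the Hox clusters. The question was what the loss of each miR-196 gene, alone and combined, does to the transcriptome of the sorted cells. The a1 and a2 alleles carried GFP and the b allele carried none, so the sorted cells of every embryo were those in which an a1 or a2 GFP allele was active. Where a1 or a2 homozygotes were compared with heterozygotes, the homozygotes also held more GFP alleles. The design does not separate allele loss from a change in the cells sorted in those comparisons. The 10 genotypes were a1 heterozygotes, a1 homozygotes, a2 heterozygotes and a2 homozygotes (5 embryos each), and 6 combined genotypes of 4 embryos each, named here a1-het a2-het, a1-het a2-hom, a1-hom a2-hom, a2-het b-hom, a2-hom b-het and a2-hom b-hom. No group was wild type at all 3 genes. Controls were heterozygotes in the comparisons of a1 and a2, a2 heterozygotes with b intact in the 3 comparisons that add b loss to them, and embryos already null for another of the genes in 3 more. Each embryo was a separate biological replicate per the labels.

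Expression was given as FPKM for 22476 gene IDs, with 11279 to 11591 genes at an FPKM of at least 1 per library. The files gave no read totals, so the number of reads behind each value is unknown. Relative depth, read from the steps between the lowest FPKM values, was 0.946 to 1.22 (median 1.08) in the 32 libraries of the 7 genotypes without a mutant b allele, whose file names share 1 flow cell code. It was 0.682 to 0.821 in the 12 libraries of the 3 genotypes with a mutant b allele, which share another code. Genes listed at 0 numbered 5874 to 6221 in the first set and 6195 to 6442 in the second, and the 10 most abundant genes took 4.18% to 5.19% and 4.39% to 5.04% of the FPKM total. Comparisons of a b genotype with the a2 heterozygotes crossed flow cells, and genotype and flow cell cannot be told apart in them.

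Mir196a-1 lies on chromosome 11 (96265164 to 96265265) upstream of Hoxb9. Mir196a-2 lies on chromosome 15 (102973350 to 102973434) between Hoxc10 and Hoxc9, and Mir196b on chromosome 6 (52230081 to 52230165) within the span of Hoxa9 (mm10, GENCODE M21). The hairpins themselves were not analysed here, so the genotype labels were not checked on the targeted genes. Libraries kept no strand, so reads of overlapping antisense genes in the Hox clusters were not told apart. The main readout was a list of 8 Hox genes known or predicted as miR-196 targets (Hoxb8, Hoxc8, Hoxd8, Hoxa7, Hoxa5, Hoxa9, Hoxb6 and Hoxb7), transcription factors that pattern the trunk axis. Of these, Hoxa7 held 4 sites of the longest seed match in its annotated 3′ UTR, Hoxa9 held shorter sites only, and Hoxb8 and Hoxd8 held no exact seed site. Imperfect matches and matches outside the seed were not searched, so this does not show that Hoxb8 and Hoxd8 are not direct targets.

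Loss of a2 was compared in a2 homozygotes against a2 heterozygotes. Hand1 (chromosome 11, 57828705 to 57832818), a transcription factor of lateral plate mesoderm, rose from 26.8 ± 2.56 to 40.8 ± 3.08 FPKM (SD, n = 5 each; log2 fold change 0.59, adjusted p = 0.0344, limma), with all homozygotes above all heterozygotes. It was the single gene of 11456 tested that passed, with 607 at an unadjusted p below 0.05. Its call ended without a filter (limma adjusted p = 0.125), with the second code of the file names as a covariate (0.0641) and without any of 7 of the 10 embryos (up to 0.166), at log2 fold changes of 0.56 to 0.61. Of 100 splits of these embryos 6 called at least 1 gene. Hoxb8 (chromosome 11, 96281905 to 96285315) ranked next and was 62.1 ± 5.01 against 45.1 ± 3.36 FPKM, again without overlap (log2 fold change 0.45, limma adjusted p = 0.0756), and Hoxc8 (chromosome 15, 102990607 to 102994111) was 34.1 ± 5.73 against 23.4 ± 4.24 (0.53, adjusted p = 0.604). Adjusted over the list alone, both rose, as 2 of the 8 Hox targets, against 0 over all genes. The list as a set ranked higher than other genes by camera (limma; adjusted p = 0.00165), but not with an estimated correlation (adjusted p = 0.577).

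The posterior Hox genes of groups 10 to 13, which pattern the lumbar to caudal axis, lay lower in the a2 homozygotes. Hoxd11 was 106 ± 3.86 against 123 ± 5.84 FPKM and Hoxd13 was 40.4 ± 5.46 against 50.8 ± 3.85. Of 10 members 5 fell adjusted over the list alone (0 over all genes by limma), and the set was lower by camera (adjusted p = 1.27e-06), a call that held with an estimated correlation (adjusted p = 0.0254). Other genes with the smallest p were Prtg (log2 fold change 0.24), Bnc1 (0.38) and Tmem88 (0.25) on the higher side, and Jarid2 (-0.24), Apol7d (-0.33), Sept8 (-0.18) and Epha1 (-0.25) on the lower; none of them passed by limma (smallest adjusted p among them 0.151). The groups did not overlap for 121 genes, 1.1% of those tested, where chance gives 0.79%. The authors' deposited table called 36 genes for this comparison (20 higher and 16 lower), Hoxb8 and Hoxc8 among them.

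**Figure D1:**
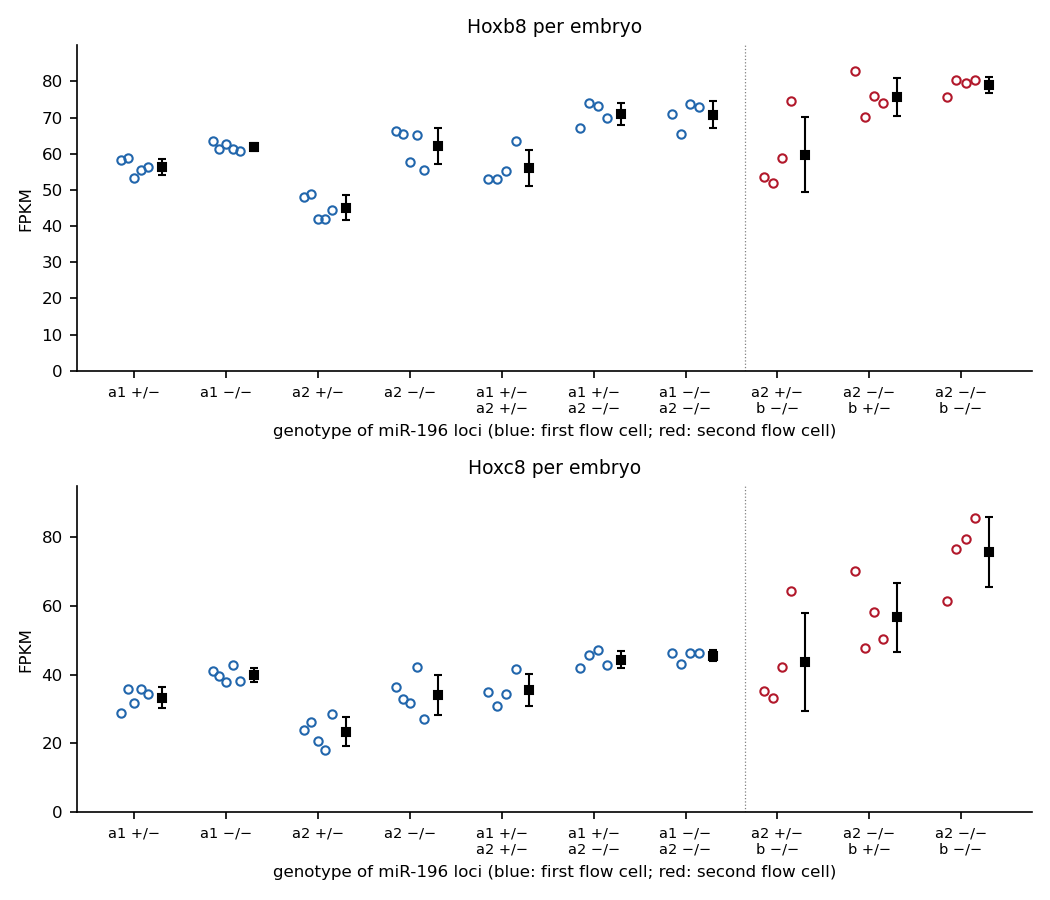
FPKM of Hoxb8 and Hoxc8 in each embryo (points) by genotype, with the mean and SD (bars) on linear axes; blue marks the first flow cell and red the second. Hoxb8 averaged 45.1 in a2 heterozygotes, 62.1 in a2 homozygotes and 79.0 in a2-hom b-hom embryos, and Hoxc8 averaged 23.4, 34.1 and 75.8.

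The same loss of a2 was measured on an a1 heterozygous background, in a1-het a2-hom against a1-het a2-het embryos. Hoxb8 was 71.1 ± 3.13 against 56.1 ± 4.96 FPKM and Hoxc8 was 44.4 ± 2.52 against 35.5 ± 4.56 (n = 4 each), both without overlap. These 2 Hox targets rose when adjusted over the list alone. No gene of 11515 passed over all genes by limma, with 541 at an unadjusted p below 0.05; the authors' deposited table called 44 (24 higher and 20 lower). Genes of cholesterol synthesis lay higher, but followed the second code of the file names, as was seen afterwards. All 4 a1-het a2-het embryos carry one code and 3 of the 4 a1-het a2-hom embryos the other. Over all 12 embryos of the a1 a2 series the list mean of log2(FPKM + 1) was 5.23 to 5.38 in the 7 embryos with the first code, 3 of them homozygous for a2 loss, and 5.46 to 5.60 in the 5 with the other. Hmgcs1, which makes the precursor of mevalonate, was 144 ± 14.8 against 118 ± 8.64 FPKM. Adjusted over the list alone 10 of 13 rose, and camera placed the set higher (adjusted p = 9.44e-15) though not with an estimated correlation (adjusted p = 0.311).

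Scd1, a fatty acid desaturase under the same sterol control, had the smallest p on the higher side (41.7 ± 3.42 against 31.5 ± 1.28 FPKM, adjusted p = 0.588, limma), followed by Tmem246, Sgsm3 and Map3k5 (log2 fold changes 0.57, 0.27 and 0.39). Col24a1, a collagen gene listed as a miR-196 target, had it on the lower side at 0.648 ± 0.12 against 1.59 ± 0.31, followed by Pdhx, Rab40c, Hist1h2bc and Cd83 (-0.26, -0.22, -0.39 and -0.35). Markers of other cell types lay lower: the neural crest genes Erbb3 (3.64 ± 0.26 against 4.70 ± 0.42 FPKM) and Sox10 (9.32 ± 0.63 against 12.1 ± 1.75) fell, adjusted over the list alone (2 of 9, with 0 over all genes by limma), as did 2 of 11 endothelial genes. Camera placed both sets lower (adjusted p = 1.51e-06 and 1.30e-05), but not with an estimated correlation (adjusted p = 0.311 and 0.399).

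Fitting both backgrounds together (18 embryos) raised the precision of the a2 comparison. Hoxb8 rose by 0.40 on the log2 scale (adjusted p = 8.30e-04, limma), and Cd83, a surface protein of immune cells, fell by 0.26 (adjusted p = 0.0411, limma). These 2 genes were the only ones called of 11506, with 495 at an unadjusted p below 0.05. Cd83 lost its call at a pseudocount of 0.1 (limma adjusted p = 0.0661), without a filter (0.0617), with the second file-name code as a covariate (log2 fold change -0.20, 0.438) and without any of 14 of the 18 embryos, while Hoxb8 kept its call in each of these. Hoxc8 had a log2 fold change of 0.44 (limma adjusted p = 0.240) and passed adjusted over the list alone, with Hoxb8, as 2 of 8. Ing5, a chromatin reader among the listed targets, had 0.14, and Cep120 and Prtg had 0.11 and 0.27; on the lower side were Apol7d (-0.27), Kcnab3 (-0.31), Pgm2 (-0.18) and Sema4g (-0.34). Posterior Hox genes fell in 5 of 10 members adjusted over the list alone (0 over all genes by limma; camera adjusted p = 3.71e-07, and 0.122 with an estimated correlation).

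The test of the difference between the backgrounds called no gene by limma, with 638 at an unadjusted p below 0.05, so a difference of the a2 effect was not shown for any gene. The log2 difference for Hoxb8 was -0.11 and for Hoxc8 -0.20. Among the lists cholesterol synthesis had the smallest p, and the file-name code described above bears on it in the same way. Adjusted over the list alone 11 members had a larger fold change on the a1 heterozygous background, Insig1 by 0.41 and Hmgcs1 by 0.37 (camera adjusted p = 1.61e-15, and 0.138 with an estimated correlation). Scd1 (0.48), Nsdhl (0.40), Srebf2 (0.21), Scd2 (0.24) and Ppp1r10 (0.35) had the smallest p on that side, and Pld6 (-0.73), Nptn (-0.34), Ube2v1 (-0.35), Gabra3 (-0.69) and Hapln1 (-0.50) on the other. Endothelial genes differed the other way in 4 members, among them Cldn5 (-0.74; camera adjusted p = 5.87e-08, and 0.138 with an estimated correlation).

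Loss of a1 was compared in a1 homozygotes against a1 heterozygotes. Hoxb9, the Hox gene next to Mir196a-1, had the smallest p on the higher side, at 325.5 ± 22.1 against 228.7 ± 20.4 FPKM (n = 5 each, no overlap; log2 fold change 0.51, adjusted p = 0.0515, limma). Rsad1, 1.7 Mb away on the same chromosome, had it on the lower side at 1.37 ± 0.07 against 2.32 ± 0.21 (-0.49, limma adjusted p = 0.0511). No gene of 11488 passed, with 544 at an unadjusted p below 0.05, while the authors' deposited table called 33 (23 higher and 10 lower), Hoxb9 among them. Hoxc8 was 39.8 ± 2.09 against 33.3 ± 3.09 FPKM and Hoxb8 was 61.9 ± 1.09 against 56.5 ± 2.23, both without overlap. Adjusted over the list alone these 2 of the 8 Hox targets rose, and camera placed the list higher (adjusted p = 3.50e-05; 0.480 with an estimated correlation). The neighbours of Mir196a-1 (Hoxb7, Hoxb8 and Hoxb9) all rose adjusted over the list alone, and this set kept its call with an estimated correlation (camera adjusted p = 0.0428).

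Hoxb9 separated the embryos by the mutant a1 allele in every series. Its FPKM was 194 or more in all 22 embryos with a mutant a1 allele and 82.7 or less in the 22 others, in which a1 was intact. Levels were 211.6 ± 16.7 in a1-het a2-het, 235.7 ± 29.8 in a1-het a2-hom and 298.5 ± 27.7 in a1-hom a2-hom embryos (n = 4 each), against 70.2 ± 1.23 in a2 heterozygotes (n = 5). The sorted cells of the 2 kinds of embryo were chosen by different GFP alleles, so this difference was not tested. Other genes with the smallest p after a1 loss were Foxn3, Pfkp, Gnb4 and Trim3 (log2 fold changes 0.53, 0.45, 0.16 and 0.18), and Slfn9, Chd3, Serinc2 and Impa1 (-0.79, -0.25, -0.26 and -0.31). The endothelial genes Tie1 and Cdh5 were 3.47 ± 0.40 and 7.41 ± 0.85 against 2.59 ± 0.40 and 5.97 ± 1.02 FPKM; 6 of 11 endothelial genes rose adjusted over the list alone, with 0 over all genes by limma (camera adjusted p = 1.30e-09, and 0.279 with an estimated correlation). The endothelial list mean, looked at afterwards, was 2.31 to 3.14 in all embryos with a mutant a1 allele. It was 0.918 to 1.34 in the a2 heterozygotes and homozygotes of the same flow cell, so it differed with the GFP allele used for sorting. The a1 homozygotes and heterozygotes did not overlap for 93 genes, 0.81% of those tested, where chance gives 0.79%.

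**Figure D2:**
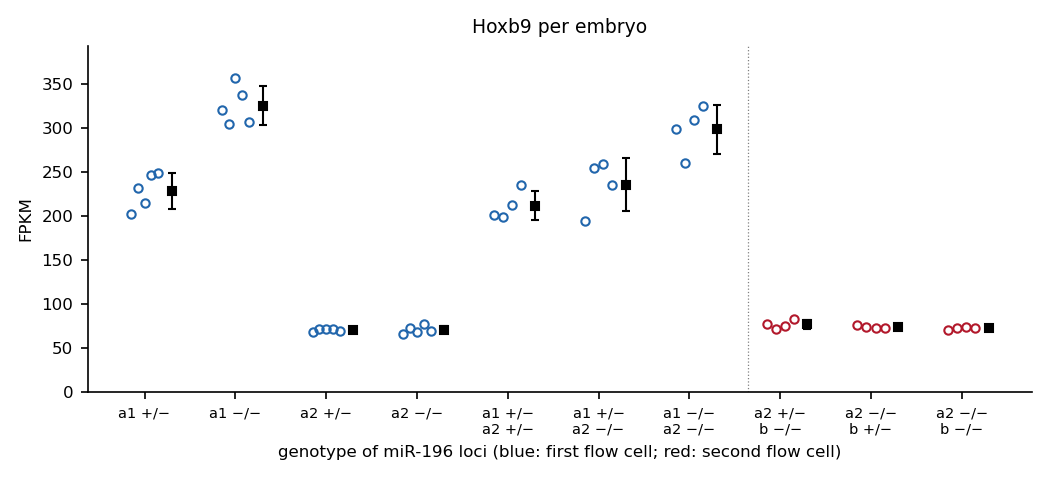
FPKM of Hoxb9 in each embryo (points) by genotype with the mean and SD (bars), on a linear axis. The 22 embryos with a mutant a1 allele sat at 194 or more and the 22 others at 82.7 or less.

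Loss of both a1 and a2 was compared in a1-hom a2-hom against a1-het a2-het embryos. All a1-het a2-het embryos share one short file-name code and the a1-hom a2-hom embryos are divided between it and another, so code and genotype overlap in part. Segmentation genes of the presomitic mesoderm, the tissue that forms somites, lay lower. The Notch ligands Dll1 and Dll3 were 33.2 ± 3.63 against 47.9 ± 3.39 and 23.6 ± 4.09 against 32.5 ± 0.59 FPKM (n = 4 each), and the T-box gene Tbx6 was 23.7 ± 4.67 against 32.6 ± 1.99. Of 17 segmentation genes 8 fell adjusted over the list alone, as did 8 of 10 FGF feedback genes, such as Spry4 (5.61 ± 0.59 against 9.18 ± 1.53), and 9 of 13 hypoxia and glycolysis genes. Camera placed the 3 sets lower (adjusted p = 2.41e-11, 8.97e-09 and 3.33e-09), but none with an estimated correlation (adjusted p = 0.135 in each). No gene of 11535 passed over all genes by limma (smallest adjusted p = 0.169), with 830 at an unadjusted p below 0.05. The authors' deposited table called 98, 31 higher and 67 lower.

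Neural tube genes lay higher in the same embryos. Pax6, which patterns the ventral neural tube, was 16.8 ± 1.02 against 13.1 ± 0.96 FPKM, Sox2 was 49.7 ± 4.36 against 39.4 ± 3.40 and Dbx1 was 3.76 ± 0.08 against 2.21 ± 0.55. Of the 15 listed 7 rose adjusted over the list alone (camera adjusted p = 9.25e-08, and 0.116 with an estimated correlation), and 5 endothelial genes rose as well (1.80e-08, and 0.234 with an estimated correlation). Hoxb8 was 70.9 ± 3.70 against 56.1 ± 4.96 and Hoxc8 was 45.5 ± 1.66 against 35.5 ± 4.56, without overlap; they were the 2 Hox targets that rose adjusted over the list alone, with 0 of the 8 over all genes by limma. Hoxb9 (log2 fold change 0.49), Elavl4 (0.47), Celsr2 (0.39) and Fndc5 (0.44) had the smallest p on the higher side, and Pgm2 (-0.34), Gstm6 (-0.38) and Foxc1 (-0.32), a regulator of somites, were on the lower side with Dll1 and Spry4. The groups did not overlap for 436 genes, 3.78% of those tested, where chance gives 2.86%.

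Across the 12 embryos with 2, 3 or 4 mutant a1 and a2 alleles, the slope per allele passed for no gene of 11524 by limma, with 616 at an unadjusted p below 0.05. The slope of Dll1 was -0.26, that of Lfng -0.36 and that of the Notch target Nrarp -0.28 (log2 per allele). Allele number overlaps in part with the second file-name code, which all 4 a1-het a2-het embryos share. Dll1 was 51.52 FPKM in the a1-het a2-hom embryo with that code and 34.56 to 42.45 in the 3 with the other. With the first code it was also lower in the a1-hom a2-hom embryos (36.78 and 34.08). Adjusted over the list alone 10 segmentation genes fell with allele number, with 9 hypoxia and glycolysis genes and 4 FGF feedback genes (camera adjusted p = 5.56e-12, 3.98e-10 and 2.30e-08), but no set passed with an estimated correlation (adjusted p = 0.102 in each). Hoxb8 and Hoxc8 had slopes of 0.17 and 0.18 and rose adjusted over the list alone. Hoxb9 (0.25), Ing5 (0.10), Adcyap1r1 (0.16), Upk3b (0.21) and Ubxn8 (0.11) had the smallest p on the higher side, and Pgm2 (-0.17), Foxc1 (-0.16), Mre11a (-0.11) and Ddit4 (-0.40) with Dll1 on the lower.

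The added loss of a1 on an a2 null background, in a1-hom a2-hom against a1-het a2-hom embryos, left the Hox targets level. Hoxb8 averaged 70.9 and 71.1 FPKM and Hoxc8 45.5 and 44.4, and 0 of the 8 passed over all genes or over the list alone (limma). Endothelial markers stood out: Emcn was 6.88 ± 0.82 against 4.57 ± 0.48 FPKM, Esam was 5.19 ± 0.42 against 3.71 ± 0.38 and Cldn5 was 10.6 ± 1.48 against 7.56 ± 0.63 (n = 4 each). All 11 endothelial genes rose adjusted over the list alone (camera adjusted p = 4.25e-21, and 0.155 with an estimated correlation). This list differed with the GFP allele used for sorting, and the a1-hom a2-hom embryos held more a1 GFP alleles. Loss of a1 and a change in the cells sorted were therefore not separated. Of the FGF feedback genes 5 fell adjusted over the list alone, among them Dusp4 (35.3 ± 4.75 against 45.2 ± 2.3) and Etv4 (15.9 ± 2.16 against 19.5 ± 1.44; camera adjusted p = 2.81e-11, and 0.155 with an estimated correlation). No gene of 11527 passed by limma, with 366 at an unadjusted p below 0.05. Col24a1 (0.62), Plvap (0.27) and Dcn (0.54) with Emcn and Esam, and Gstm6 (-0.41), Tmem246 (-0.57), Hoxc9 (-0.21) and Cnot6l (-0.31) with Dusp4, had the smallest p.

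The role of b was addressed by 3 comparisons with the a2 heterozygotes, which cross flow cells. The first was loss of b on an a2 heterozygous background (a2-het b-hom). Hoxa9, the Hox gene that spans Mir196b, was at 122.7 ± 25.8 FPKM in these embryos against 75.4 ± 10.1 (n = 4 and 5, log2 fold change 0.68, adjusted p = 0.0353, limma). Whether b loss or the flow cell gave this difference cannot be told. Hoxc8 was 43.7 ± 14.3 against 23.4 ± 4.24, Hoxa7 was 96.6 ± 27.8 against 59.7 ± 9.18 and Hoxb8 was 59.8 ± 10.4 against 45.1 ± 3.36, each without overlap. Of the 8 Hox targets 1 rose over all genes and 7 adjusted over the list alone (camera adjusted p = 1.39e-06, and 0.582 with an estimated correlation).

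Cardiac muscle genes led the calls of the same comparison. The myosin light chain genes Myl2 and Myl4 were 13.5 ± 11.7 and 11.03 ± 8.28 FPKM against 1.63 ± 1.26 and 1.52 ± 0.92, and Nppa, which encodes the atrial natriuretic peptide, was 4.03 ± 2.96 against 0.12 ± 0.05. Fold changes on the log2(FPKM + 1) scale understate genes this low. Tnnt2, Tnnc1, Myl3 and Myh7 were among the 10 largest rises as well, leaving aside genes with provisional names (log2 fold changes 1.64, 1.63, 1.43 and 1.42), with Capn11 (1.68) and Hist1h2ag (0.85). Of 7 cardiac list genes tested 4 rose over all genes and 7 adjusted over the list alone (camera adjusted p = 1.73e-08, and 0.582 with an estimated correlation). The largest falls were in Gltp (14.2 ± 4.61 against 29.0 ± 0.68), the ribosomal gene Rplp0 (696.4 ± 166.2 against 1147 ± 58.1), the p53 target Pmaip1 (17.4 ± 1.95 against 29.4 ± 2.57), Sorbs3, Idua, Spg11, the notochord gene Noto, Snai1, Aldh1b1 and Crlf2. Eif3j2 (5.57 ± 1.70 against 0.85 ± 0.18) and Rplp0 share sequence with near-identical copies, so their levels are uncertain. Limma called 310 of 11441 genes (176 higher and 134 lower), against 435 in the authors' deposited table (281 and 154). The count was unstable: 29 to 861 with 1 embryo left out, 127 without a filter and 818 with all 44 libraries in 1 fit. It was 2 with the cardiac list mean as a covariate, which was chosen after the result was seen and follows genotype closely. The split was 300 higher and 107 lower after rescaling the libraries to a common median ratio, and 230 and 130 after quantile normalization. With all 44 libraries in 1 fit it turned to 332 higher and 486 lower.

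The other 2 groups had loss of a2 with 1 b allele (a2-hom b-het) and loss of all a2 and b alleles (a2-hom b-hom). Their means over the 8 Hox targets were the highest in the series (log2 5.92 and 6.07), although Hoxa9 and Hoxb7 were highest in a2-het b-hom embryos. Genotype and flow cell cannot be told apart in their comparisons with the a2 heterozygotes. Hoxc8 was 56.7 ± 10.2 and 75.8 ± 10.2 FPKM (n = 4 each) against 23.4 ± 4.24 in the a2 heterozygotes (n = 5), with log2 fold changes of 1.24 and 1.66 (adjusted p = 9.58e-04 and 8.67e-05, limma). Hoxb8 was 75.8 ± 5.26 and 79.0 ± 2.22 against 45.1 ± 3.36 (0.74 and 0.80, limma adjusted p = 1.10e-04 and 1.80e-05). Hoxa7 was 97.7 ± 17.0 and 112 ± 14.8 against 59.7 ± 9.18, and Hoxd8, Hoxb6, Hoxa9 and Hoxb7 rose too, while Hoxa5 had log2 fold changes of 0.09 and 0.22 and did not pass. In each comparison 7 of the 8 Hox targets rose over all genes and adjusted over the list alone. With the mean of a cardiac gene list as a covariate, chosen after the result was seen, none of the 7 passed, and the fold changes of 5 and 1 of them turned negative. That mean follows genotype closely, from 0.98 in the a2 heterozygotes to 3.97 and 3.64. Among embryos of 1 genotype it also went with the Hox target mean in part, which was not tested. Camera placed the list higher (adjusted p = 1.75e-06 and 3.37e-08), but not with an estimated correlation (adjusted p = 0.345 and 0.232).

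Posterior Hox genes fell in the same embryos, by 7 members in each comparison over all genes. Hoxd12 fell from 12.5 ± 4.44 FPKM to 1.79 ± 1.47 and 2.19 ± 1.14, Hoxc11 from 33.4 ± 1.53 to 19.8 ± 5.06 and 22.9 ± 1.56, and Hoxd13 from 50.8 ± 3.85 to 32.8 ± 8.09 and 30.5 ± 6.59 (camera adjusted p = 0.00153 and 1.37e-04, and 0.345 and 0.0964 with an estimated correlation). Of 12 tested genes of lateral plate mesoderm and limb bud 5 rose in each comparison over all genes, and 0 and 1 fell (camera adjusted p = 0.0292 and 0.0896, and 0.436 and 0.568 with an estimated correlation). Hand1 rose to 64.9 ± 12.5 and 74.7 ± 3.01 FPKM from 26.8 ± 2.56, and its relative Hand2 to 54.1 ± 5.78 and 50.3 ± 3.96 from 31.9 ± 4.04 (all limma adjusted p below 0.05; the largest of the 4 was 0.00201). Among the other listed targets, the cell cycle inhibitor gene Cdkn1b rose to 14.9 ± 1.64 and 18.4 ± 1.09 FPKM from 10.3 ± 1.00. In the a2-hom b-hom embryos 4 of 14 such targets rose over all genes, and 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0433, and 0.232 with an estimated correlation).

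Cardiac genes were again the largest rises. Myl7, an atrial myosin light chain gene, was 101 ± 53.3 FPKM in a2-hom b-het and 77.5 ± 57.3 in a2-hom b-hom embryos against 2.77 ± 1.96, Myl2 was 41.9 ± 17.5 and 36.8 ± 24.5 against 1.63 ± 1.26, and Nppa was 11.8 ± 4.82 and 10.5 ± 4.06 against 0.12 ± 0.05. Myl4, Tnnt2, Tnnc1, Myl3, Csrp3, Myh6 and Myh7 completed the 10 largest rises in both, again without genes of provisional name, with log2 fold changes of 2.94 to 4.18 and 2.52 to 3.79. All 8 and 7 cardiac list genes tested rose over all genes and adjusted over the list alone (camera adjusted p = 3.56e-13 and 3.49e-09, and 0.316 and 0.232 with an estimated correlation). The keratin genes Krt8 and Krt18 also rose (0.64 and 0.74 in the first comparison), as did the endothelial genes Tek and Kdr and, in a2-hom b-hom embryos, the embryonic globin gene Hbb-bh1 (40.3 ± 23.8 against 9.76 ± 4.58).

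Agpat9, a gene of glycerolipid synthesis, fell to 2.86 ± 2.15 and 1.35 ± 0.30 FPKM from 7.77 ± 0.43, and Gltp to 14.9 ± 3.38 and 12.7 ± 0.68 from 29.0 ± 0.68. Pla2g4b, Kcnab3, Aldh1a2 (which makes retinoic acid), Wnt1, Pmaip1 and mt-Nd3 were the other large falls in a2-hom b-het embryos. In a2-hom b-hom embryos they were the platelet genes Tubb1, Plek, Ppbp, Itgb3 and Itga2b and the matrix gene Thbs1 (log2 fold changes of -1.36 to -1.77). Cholesterol synthesis genes fell in the a2-hom b-hom embryos, 11 of the list over all genes and 12 adjusted over the list alone, Lss from 20.5 ± 0.84 to 16.9 ± 0.67 (camera adjusted p = 3.63e-07, and 0.232 with an estimated correlation). Limma called 1630 of 11514 genes for a2-hom b-het (812 higher and 818 lower) and 2067 of 11472 for a2-hom b-hom (1068 and 999). The splits after rescaling to a common median ratio were 983 and 619, and 1152 and 875. After quantile normalization they were 864 and 880, and 1045 and 1180. With all 44 libraries in 1 fit they were 958 and 1301, and 1131 and 1361. Leaving out 1 embryo gave 693 to 2051 and 1096 to 2936 genes. With the cardiac list mean as a covariate, which follows genotype closely, 2 and 6 genes passed. The authors' deposited tables called 994 (615 higher and 379 lower) and 1113 (686 and 427).

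**Figure D3:**
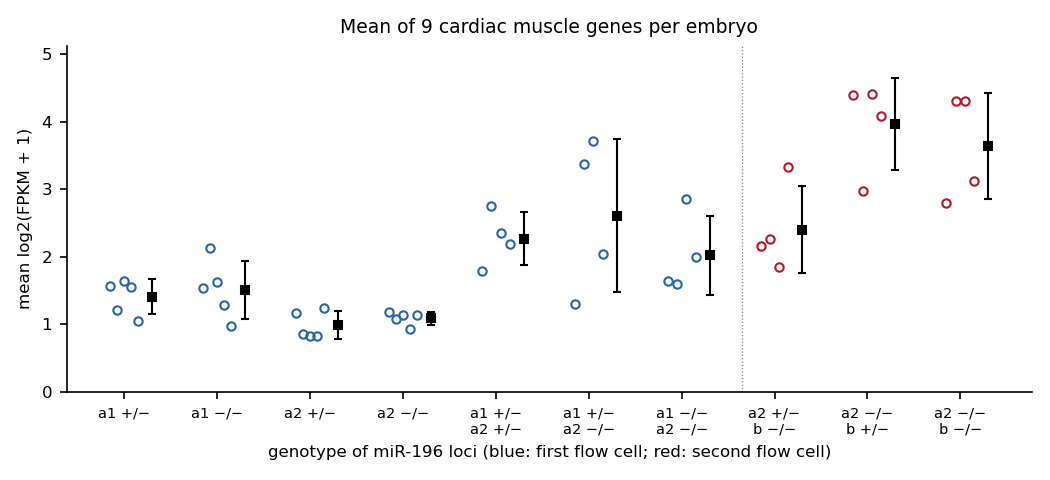
Mean log2(FPKM + 1) of the cardiac gene list in each embryo (points) by genotype with the mean and SD (bars). The a2 heterozygotes averaged 0.98, the a2-het b-hom embryos 2.40, the a2-hom b-het embryos 3.97 and the a2-hom b-hom embryos 3.64.

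These embryos differed from the a2 heterozygotes in other measured ways. Gm8730, a processed copy of Rplp0, was at 1.52 to 2.85 FPKM in the 32 libraries without a mutant b allele and at 68.0 to 150.5 in the 12 others, while Rplp0 was at 1043 to 1379 and at 556.6 to 961.5. Pcna-ps2, a copy of Pcna, was at 1.90 to 3.24 and at 22.1 to 53.4, and Eif3j2 at 0.63 to 1.21 and at 4.46 to 8.09. Gltp lies close to Rplp0 on chromosome 5 and was at 24.3 to 30.7 and at 11.2 to 20.99. Mcm8, close to Pcna on chromosome 2, was at 16.5 to 21.1 and at 10.8 to 15.7, and Spg11 and Pla2g4b lie close to Eif3j1 on the same chromosome. Gm8730 had the largest log2 fold change of all called genes in each of the 3 comparisons with the a2 heterozygotes, and copy and parent share reads, so neither level is certain. Gm8730, Pcna-ps2 and Mcm8 were picked after their values had been seen.

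Comparisons inside the second flow cell asked for the added loss of 1 gene. For loss of a2 on a b null background (a2-hom b-hom against a2-het b-hom) the groups share no second file-name code, so a2 genotype and code cannot be told apart. Cdkn1b (chromosome 6, 134920401 to 134925513), which encodes the cell cycle inhibitor p27, was higher at 18.4 ± 1.09 against 12.3 ± 0.41 FPKM (n = 4 each, no overlap; log2 fold change 0.54, adjusted p = 0.0237, limma). Bnc1 rose from 2.56 ± 0.14 to 4.28 ± 0.22 (limma adjusted p = 0.0411) and Sema3a, an axon guidance gene, fell from 18.7 ± 0.40 to 14.1 ± 0.65 (adjusted p = 0.0438). These 3 genes of 11449 passed by limma, with 982 at an unadjusted p below 0.05, and none of the 3 passed without a filter (smallest adjusted p = 0.0554, limma) or without any of 4 of the 8 embryos. Podxl, Trim55 and Hebp1 (log2 fold changes 0.33, 0.65 and 1.27), and Sema6a, Chd3, Sox3 and Trh (-0.49, -0.40, -0.41 and -0.45), came next; Hebp1 lies close to Cdkn1b. Hoxc8 was 75.8 ± 10.2 against 43.7 ± 14.3 and Hoxb8 was 79.0 ± 2.22 against 59.8 ± 10.4, and these 2 of the 8 Hox targets rose adjusted over the list alone (camera adjusted p = 0.0317, and 0.608 with an estimated correlation).

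In the same comparison Hand1 was 74.7 ± 3.01 against 38.0 ± 8.33 FPKM (adjusted p = 0.0552, limma), and 5 lateral plate genes rose adjusted over the list alone (camera adjusted p = 5.87e-04, and 0.321 with an estimated correlation). The neural tube genes Sox3 and Sox2 were 29.4 ± 1.68 against 39.4 ± 3.25 and 41.1 ± 2.98 against 52.8 ± 3.51, and 5 of that list fell adjusted over the list alone (9.12e-06, and 0.247 with an estimated correlation). Cardiac genes lay higher here too: Actc1 was 114 ± 58.4 against 39.5 ± 16.1, and 7 of 8 rose adjusted over the list alone, with 0 over all genes by limma (1.69e-06, and 0.281 with an estimated correlation). The groups did not overlap for 606 genes, 5.29% of those tested, where chance gives 2.86%.

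Loss of the second b allele on an a2 null background (a2-hom b-hom against a2-hom b-het) called no gene of 11495 by limma, with 353 at an unadjusted p below 0.05. Hoxc8 was 75.8 ± 10.2 against 56.7 ± 10.2 FPKM and Hoxb8 was 79.0 ± 2.22 against 75.8 ± 5.26, with overlap in Hoxc8 and in Hoxb8. Ypel3 (log2 fold change 0.47), Neto2 (0.21), Fam221a (0.52), Ankrd32 (0.17) and the apoptosis gene Bmf (0.19) had the smallest p on the higher side, and Dmgdh (-0.37), Ramp2 (-0.46), Rasgrp2 (-0.54), Pygl (-0.24) and Lgals3bp (-0.48) on the lower. None of the Hox targets passed over all genes or over the list alone. Camera placed them higher as a set (adjusted p = 5.37e-04), but not with an estimated correlation (adjusted p = 0.625).

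To take the embryo and not the gene as the replicate, the mean log2(FPKM + 1) of the 8 Hox targets was compared with exact two-sided permutation tests. The mean was 5.36 ± 0.17 in a2 heterozygotes and 5.86 ± 0.26, 5.92 ± 0.15 and 6.07 ± 0.12 in a2-het b-hom, a2-hom b-het and a2-hom b-hom embryos. The differences of 0.50, 0.56 and 0.71 each had the smallest exact p that 4 against 5 embryos allow, 0.00794 (0.0265 adjusted over the 10 comparisons), with 4 of 4 mutants above all controls. These comparisons share their controls and cross flow cells, so genotype and flow cell cannot be told apart in them. All a2-hom b-het and a2-hom b-hom embryos also carry a single short file-name code. Within the first flow cell the mean was 0.14 higher after a1 loss (exact p = 0.0952), 0.18 after a2 loss (exact p = 0.135), 0.13 after a2 loss on the a1 heterozygous background (exact p = 0.0857) and 0.12 after double loss (exact p = 0.143). Within the second flow cell it was 0.21 higher for loss of a2 on the b null background (exact p = 0.229) and 0.15 for the second b allele (exact p = 0.200). Loss of a1 on the a2 null background gave -0.01 (exact p = 0.857). The smallest exact p for 4 against 4 embryos is 0.0286 and for 5 against 5 it is 0.00794.

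**Figure D4:**
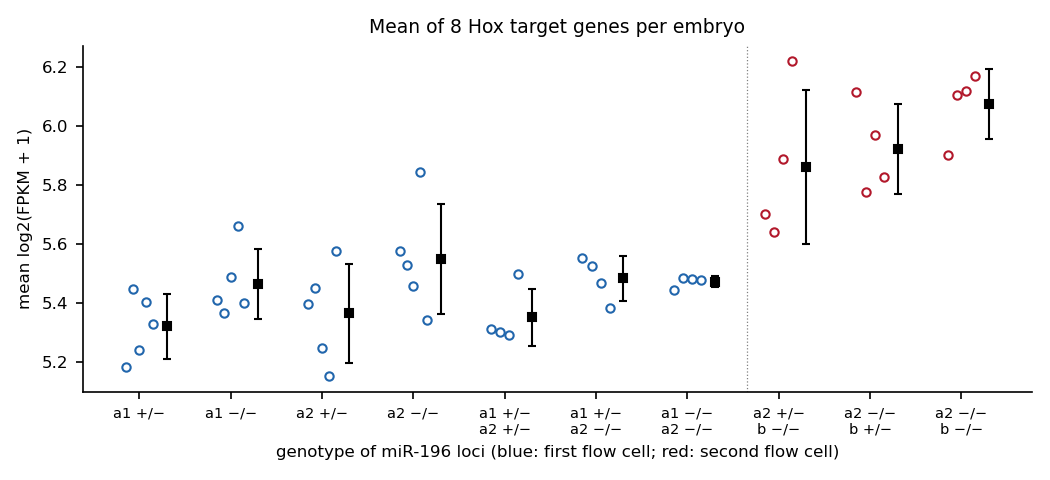
Mean log2(FPKM + 1) of the 8 Hox targets in each embryo (points) by genotype with the mean and SD (bars). The a2 heterozygotes averaged 5.36 and the a2-hom b-hom embryos 6.07.

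Genes with a miR-196 seed match in the longest annotated 3′ UTR were tested as 1 large set of about 900 tested genes per comparison. After double loss of a1 and a2, 59.9% of the 913 matched genes had a positive fold change, against 51.0% of the others (camera in limma, p = 0.0279, adjusted over the 13 fits 0.215; 2 of 35 permutations of the embryos gave a p as small, the real one included). The slope per mutant allele gave 59.8% and 51.0% (p = 0.0331, adjusted 0.215; 5 of 100 permutations, the real one included). In the other 11 fits the unadjusted p was 0.149 or more. A comparison set held genes with a let-7 site (CTACCTC) and no miR-196 8mer or 7mer matching positions 2 to 8. That set, for which no permutation was run, gave camera p = 0.689 and 0.71 in those 2 fits. The let-7 site and the miR-196 7mer (ACTACCT) share the bases CTACCT. Every gene of the comparison set therefore held a partial miR-196 match, and the set is not a neutral control.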

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

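The tests of other splits of the embryos and of depth, and the windows for a1 loss on the a2 null background, a2 loss and the second b allele, were written before their results were seen. The other tests in this part (flow cell, strain segments, the window and the Hoxb9 tests for a1 loss, heart cells and the second GFP copy) were chosen after.

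Many genes were called between the a2 b embryos and the a2 heterozygotes (310, 1630 and 2067), and at most 3 by a comparison inside the second flow cell. Chance alone is an unlikely source of the 3 counts, since 1 of 100 splits, the real one, gave as many (highest other 3, 76 and 278). The 13 fits were checked without adjustment. These 3 comparisons share their controls, and the real split is also that of the flow cells. Lower depth predicts few calls among abundant genes, but 22.18% of genes at a mean FPKM of at least 50 were called after loss of a2 and b, against 13.82% at 1 to 5. The calls were thus not confined to low genes. Abundant genes are measured with less noise whatever the cause of a difference, so these shares cannot decide on depth. Chromosome segments of another strain may account for part: in the 12 embryos of the second flow cell, genes within 5 Mb of Rplp0, Pcna and Eif3j1 followed the copies Gm8730, Pcna-ps2 and Eif3j2 more closely than 98.06%, 98.13% and 100% of other windows (55.94% for the first at 10 Mb, and 82.59%, 9.91% and 6.14% in the 32 other embryos). Genotype, flow cell, file-name code and strain background cannot be told apart for the remaining genes, and no window of 20 genes held more calls than the highest of 1000 shuffles (6, 12 and 12 against 6, 13 and 14, with shuffled medians of 4, 9 and 11), which b loss equalled.

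Genes near the targeted loci ranked high: the mean absolute t of genes 1 to 10 Mb from Mir196a-1 exceeded that of 95.49% of windows elsewhere for a1 loss and 98.47% for a1 loss on the a2 null background. A linked segment around the targeted allele may explain it, but the genes there at an unadjusted p below 0.01 (3 and 4) were different ones, and Rsad1, 1 of the 3, was at 1.05 to 1.33 FPKM in all 12 embryos of the a1 a2 series and did not follow a1 in them. For a2 loss and the second b allele the figures were 88.77% and 80.19%, which leaves the same explanation open there. A general effect of miR-196 on Hoxb9 is argued against by its log2 fold change of 0.035 after loss of a2 and b, although a1 was intact in those embryos. An effect of the inserted allele on its neighbour may explain Hoxb9, whose log2 fold change was 0.344 for a1 loss on the a2 null background.

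Cardiac muscle genes were higher in the a2 b embryos, with list means of 2.40, 3.97 and 3.64 against 0.98 in a2 heterozygotes (exact two-sided p = 0.00794 for each, the smallest possible). Heart cells in the sorted fraction may explain it. Of the tested cardiac genes outside the fixed list 76.5% of 17 had a log2 fold change above 1 in a2-hom b-het embryos. The share was 73.3% of 15 in a2-hom b-hom embryos, and 30% of 10 in a2-het b-hom embryos, whose list mean was also lower. Of 23 such genes listed 8 were tested for a2 loss, so some may have passed the filter only through high values in the a2 b embryos. These shares therefore cannot decide, and a change of expression in the sorted cells would raise the same genes. A second GFP copy is argued against only where a1 and b were intact, by the a2 homozygotes, whose mean differed from that of heterozygotes by 0.11 (95% interval -0.125 to 0.345). On the a1 heterozygous background the difference for a2 loss was 0.341 (95% interval -1.129 to 1.811), too wide to decide. Flow cell is open: inside the second flow cell the difference for a2 loss was 1.23 (exact two-sided p = 0.0857, smallest possible 0.0286). Loss of the second b allele inside that flow cell gave -0.33 (95% interval -1.60 to 0.94, exact two-sided p = 0.6), and other effects of b loss stay untested, since b genotype and flow cell go together.

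Whether chance can be excluded was asked of the other counts of called genes. For a2 loss combined over the backgrounds 1 of 100 splits, the real one, gave as many genes as the real 2 (highest other 1). With so small a lead and 13 fits checked without adjustment, chance is not excluded for this count. For a2 loss 6 of 100 splits called at least 1 gene (highest other 33). For a2 loss on the b null background 2 of 35 called at least 3 (highest other 3), so chance is not excluded for these counts either. Where the real count was 0 every split reached it: 100 of 100 for a1 loss (highest other 902), the difference between backgrounds (1189) and the allele trend (3), and 35 of 35 for a2 loss on the a1 heterozygous background (13), double loss of a1 and a2 (88), the second b allele (8) and a1 loss on the a2 null background (1246). The splits with 902, 1246 and 1189 genes point to a structure of the samples other than genotype. The first joined a1 heterozygous embryos 4 and 5 with a1 homozygous embryos 2, 3 and 5, which share 1 short file-name code, but a1 homozygous embryo 4 carries that code too and lay on the other side. The split with 1246 genes did not follow the codes.

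In the same count for gene lists the real split called more than any other for a2 loss on the a1 heterozygous background (17 lists, highest other 16, 1 of 35 splits), double loss of a1 and a2 (19 and 18, 1 of 35), a2 loss on the b null background (15 and 11, 1 of 35) and the allele trend (18 and 17, 1 of 100). Most of these leads are narrow and the 13 fits were checked without adjustment, so chance is not excluded there. A difference between the short file-name codes is not excluded either. The groups share no code in a2 loss on the b null background, 7 of 8 embryos divide by code in a2 loss on the a1 heterozygous background, and code and genotype overlap in part in the other 2 fits. Other splits also reached the real count for a1 loss (10 and 16, 35 of 100), a2 loss (8 and 17, 30), b loss (8 and 15, 48), a2 loss with 1 b allele (14 and 21, 11), loss of a2 and b (10 and 16, 36), the combined fit (14 and 16, 7) and the difference between backgrounds (7 and 21, 56). They did so too for the second b allele (12 and 16, 11 of 35) and a1 loss on the a2 null background (12 and 16, 10 of 35). Most splits without meaning called several lists, so a camera call with the preset correlation is weak evidence on its own here.

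For the seed-matched genes, 2 of 35 splits gave a p as small as the 0.0279 of double loss (smallest other 0.0209) and 5 of 100 as small as the 0.0331 of the trend (smallest other 0.0116), so chance is not excluded. The same permutation of embryos in the other fits gave 32 of 100 (a1 loss, p = 0.527, smallest other 0.162), 71 (a2 loss, 0.620 and 0.0202), 90 (b loss, 0.847 and 0.0347), 87 (a2 loss with 1 b allele, 0.868 and 0.0462), 86 (loss of a2 and b, 0.817 and 0.0110), 13 (combined, 0.149 and 0.0122) and 61 (difference, 0.529 and 0.0433). Of 35 splits the count was 12 for a2 loss on the a1 heterozygous background (0.156 and 0.0700), 21 for the second b allele (0.469 and 0.0433), 33 for a2 loss on the b null background (0.883 and 0.0599) and 19 for a1 loss on the a2 null background (0.466 and 0.0176).

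Single embryos stood apart from the others of their group in 32 of 524 groups of values tested by Dixon's ratio, where chance gives about 1 in 20, or 26.2. Embryo 4 of the a2-het b-hom group stood apart most often: Myl2 31.02 FPKM (others 6.99 to 8.61), Tnnc1 12.1 (2.41 to 3.75), Snai1 58.95 (43.05 to 44.6), Pmaip1 20.33 (16.32 to 16.63) and Hoxb7 54.49 (41.26 to 43.1). Embryo 1 of that group had Gm8730 at 68.0 (131.2 to 138.8) and Gltp at 20.99 (11.18 to 12.82). In the a2-hom b-het group embryo 3 had Eif3j1 at 4.64, Eif3j2 at 4.79 and Pla2g4b at 10.59, embryo 2 had Gltp at 19.98 and Myh7 at 3.79, and embryo 1 had Lgals3bp at 2.57. Krt8 was 39.38 in a2-hom b-hom embryo 1.

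In the a2 heterozygotes Capn11 was 0.252 (others up to 0.0131), Prtg 28.76 and Rplp0 1043 in embryo 5, Myl2 3.82 in embryo 4 and Sept8 40.14 in embryo 3. Embryo 4 of the a2 homozygotes had Hoxa5 at 43.39 and Hoxb7 at 46.52, embryo 4 of the a1 homozygotes Hoxb6 at 28.44 and Hoxb7 at 45.83, embryo 4 of the a1 heterozygotes Hoxa5 at 34.86, and embryo 2 there Pfkp at 3.74. Among the a1-het a2-het embryos, embryo 4 had Hoxb7 at 37.07 and a Hox target mean of 5.50, and embryo 3 Rab40c at 20.03. Cldn5 was 8.50 in a1-het a2-hom embryo 4 and Dcn 0.814 in embryo 2, and Hoxc8 was 42.99 in a1-hom a2-hom embryo 2 with a Hox target mean of 5.44 in embryo 1.

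By the test of the difference between the 2 a1 backgrounds the effect of a2 loss passed for 7 gene lists with the preset correlation, but for none with an estimated one (smallest adjusted p = 0.138), and 56 of 100 splits called at least 7. The lists were cholesterol synthesis (camera adjusted p = 1.61e-15), endothelium (5.87e-08), unfolded protein response (5.48e-04), BMP and TGF-beta targets (9.70e-04), neural tube (0.00415), neural crest (0.0202) and blood (0.0349). The cholesterol synthesis list followed the short file-name code in the a1 a2 series.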

How the results depend on the processing

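The cardiac list mean as a covariate was added after the result was seen, and the other alternatives were planned. The planned count-based test was not run, because the files hold FPKM and no counts.

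Of the alternatives other than leaving out a library, gene counts stayed within 1.5 times in 75 cases and moved further in 26, and the exact test of the Hox target mean gave the same call in all 20. Named genes kept direction and call in 561 cases, lost the call in 102, gained it in 17 and reversed in 27. Rescaling by the median ratio and quantile normalization moved no count beyond 1.5 times.

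A pseudocount of 0.1 called 1 gene for a1 loss, 5 for a2 loss on the b null background and 1 for the combined fit. Without a filter the counts were 0 for a2 loss, 1 for double loss of a1 and a2, 127 for b loss, 1 for the second b allele, 0 for a2 loss on the b null background and 1 for the combined fit; a mean FPKM of at least 5 gave 1 for a2 loss on the b null background. All 44 libraries in 1 fit gave 3 for a1 loss, 5 for a2 loss, 1 for double loss, 818 for b loss and 121 for a2 loss on the b null background. With the short file-name code as a covariate the counts were 0 for a2 loss, 3 for a2 loss on the a1 heterozygous background and 2 for the difference between backgrounds.

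Embryos with the same replicate number were not alike: in 0 of 10 comparisons were all pairs correlated above 0.1 (range -0.357 to 0.302), so the numbers were not taken as pairs. With a replicate block the counts were 0 for a2 loss, 3 for b loss, 975 for a2 loss with 1 b allele, 1501 for loss of a2 and b and 9 for a2 loss on the b null background.

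With an estimated correlation, camera called 1 list for a1 loss, 1 for a2 loss and 0 for each other fit. Fry called 1 for a1 loss, 1 for a2 loss, 2 for a2 loss on the a1 heterozygous background, 1 for double loss, 2 for the combined fit, 15 for a2 loss with 1 b allele and 15 for loss of a2 and b, and 0 for each other fit. For the seed-matched genes, adding 7mer-A1 sites gave camera p (no permutation was run for these) = 0.0682 for double loss and 0.0697 for the trend, and 8mer sites alone gave 0.0038 for the combined fit (0.0494 adjusted over 13 fits), which did not pass so adjusted with an estimated correlation (unadjusted p = 0.0181). At a q below 0.01 the authors' tables called 75 genes for double loss of a1 and a2, 240 for b loss, 643 for a2 loss with 1 b allele and 681 for loss of a2 and b. They called 0 for a1 loss, a2 loss and a2 loss on the a1 heterozygous background. In these 3 tables Hoxd12 had a Cuffdiff p of 5e-05, at a q of 0.0172, 0.0151 and 0.0131. No smaller p was seen among the genes looked up, so a q below 0.01 may have been out of reach there.

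The cardiac list mean as a covariate left 2 genes for b loss, 2 for a2 loss with 1 b allele, 6 for loss of a2 and b and 1 for a2 loss on the b null background. It follows genotype closely, so a call lost with it does not show a weaker effect. Directions turned for b loss in Tnnt2 (-0.079), Tnnc1 (-0.088) and Myl3 (-0.10). For a2 loss with 1 b allele they turned in Hoxa7 (-0.33), Hoxb6 (-0.080), Hoxd8 (-0.48), Hoxa9 (-0.24), Hoxb7 (-0.25), Myl7 (-0.35), Tnnt2 (-0.21), Myl3 (-0.12), Myh6 (-0.60), Hoxd12 (0.71), Agpat9 (0.86), Kcnab3 (0.32), Aldh1a2 (0.90), Wnt1 (0.63) and Gltp (0.11). For loss of a2 and b they turned in Hoxb7 (-0.082), Myl7 (-0.57), Myl4 (-0.11), Tnnt2 (-0.19), Myl3 (-0.46), Tnnc1 (-0.16), Csrp3 (-0.070), Myh6 (-0.059) and Myh7 (-0.13). None of these turned values passed. Inside groups the Hox target mean went with the cardiac mean in part, which was not tested. Embryo 4 of a2-het b-hom was highest in both (6.22 and 3.33). Embryo 2 of a2-hom b-het (5.78 and 2.98) and embryo 1 of a2-hom b-hom (5.90 and 2.80) were lowest in both. Embryo 3 of a2-het b-hom, lowest in the cardiac mean (1.85), had a Hox target mean of 5.89, above those of embryos 1 and 2.

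Leaving out 1 library moved 54 counts by more than 1.5 times and left 81 within it. The counts ranged from 29 to 861 for b loss (50, 63, 44 and 72 without a2 heterozygote 1, 2, 3 or 4, and 94, 861, 29 and 144 without a2-het b-hom embryo 1, 2, 3 or 4). They ranged from 693 to 2051 for a2 loss with 1 b allele (984, 1060, 1032 and 906 without a2 heterozygote 1 to 4, 917 and 693 without a2-hom b-het embryo 1 or 3), and from 1096 to 2936 for loss of a2 and b (1339 and 1365 without a2 heterozygote 1 or 4, 1376, 1096 and 1170 without a2-hom b-hom embryo 2, 3 or 4). For a2 loss the range was 0 to 5: 0 without a2 heterozygote 1, 2 or 4 or homozygote 1, 3, 4 or 5, and 5 without heterozygote 5. For a2 loss on the b null background it was 0 to 8: 0 without a2-het b-hom embryo 1, 2 or 3 or a2-hom b-hom embryo 3, and 8 without a2-het b-hom embryo 4.

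For the other fits the range was 0 to 11 for double loss (11 without a1-het a2-het embryo 4, 1 without a1-hom a2-hom embryo 4), 0 to 1 for a1 loss (1 without a1 homozygote 1), 0 to 1 for a1 loss on the a2 null background (1 without a1-hom a2-hom embryo 4), 0 to 2 for the second b allele (2 without a2-hom b-het embryo 3), 0 to 9 for the difference between backgrounds (9 without a1-het a2-hom embryo 1, 2 and 1 without a2 heterozygote 5 or 1), 1 to 3 for the combined fit (1 without any of 14 embryos) and 0 for a2 loss on the a1 heterozygous background and the trend. The Hox target mean ranged from 0.66 to 0.77 for loss of a2 and b, 0.49 to 0.61 for a2 loss with 1 b allele, 0.38 to 0.57 for b loss, 0.10 to 0.18 for a1 loss, 0.11 to 0.24 for a2 loss, 0.11 to 0.18 for a2 loss on the a1 heterozygous background, 0.10 to 0.17 for double loss, 0.10 to 0.22 for the second b allele, 0.14 to 0.33 for a2 loss on the b null background and -0.04 to 0.01 for a1 loss on the a2 null background. Without a1 heterozygote 2 the exact two-sided p for a1 loss was 0.0476, and without a1-het a2-het embryo 4 that for double loss was 0.0286, the smallest possible there; both are unadjusted.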

Other observations

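In this part the levels of Hand1 by genotype and the cardiac values outside the a2 b embryos were chosen after they had been seen. Within the first flow cell Hand1 averaged 26.8 FPKM in a2 heterozygotes and 40.8 in a2 homozygotes, but its mean was above both in every group with a mutant a1 allele. It averaged 45.05 and 47.26 in a1 heterozygotes and homozygotes, and 48.91, 53.19 and 55.45 in a1-het a2-het, a1-het a2-hom and a1-hom a2-hom embryos. On the a1 heterozygous background a2 loss gave a log2 fold change of 0.11 (limma adjusted p = 0.967). Within the second it averaged 38.0 in a2-het b-hom, 64.9 in a2-hom b-het and 74.7 in a2-hom b-hom embryos. Hand1 was not on the list of miR-196 targets. A difference of its a2 effect between the a1 backgrounds was not shown (log2 difference -0.47, limma adjusted p = 0.653), and its effect common to both was 0.38 (adjusted p = 0.328).

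Cardiac genes also varied among embryos without a mutant b allele. Their list mean was 2.27 ± 0.40 in a1-het a2-het, 2.61 ± 1.13 in a1-het a2-hom and 2.02 ± 0.59 in a1-hom a2-hom embryos (n = 4 each), against 0.98 ± 0.21 and 1.09 ± 0.095 in a2 heterozygotes and homozygotes (n = 5 each). These groups share the first flow cell, and no test was run between groups sorted by different GFP alleles.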
